A study of Mus musculus with 12 samples.

How the data were processed

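Genomic DNA of 12 colonic adenomas was spiked with methylation standards and cut first with SmaI, which cuts unmethylated CCCGGG sites, and then with XmaI, which cuts the methylated sites left, per the labels' protocols. Reads were trimmed with Trim Galore and aligned with Bowtie2 to mm9, per the submitters' processing notes. The versions are not given in the sources used here. The build mm9 is also named per the file headers, while the text of the extraction protocol names a rat build. The deposited counts are methylated and unmethylated reads at each of 173449 CCCGGG sites, per the file headers. The deposited percent values are a raw level (methylated reads per 100 reads) and a level adjusted by the authors for enzyme efficiency with the spiked standards, per the labels. Of the sites, 164896 were autosomal, 8435 on X and 118 on Y, and 18 further entries were standards. The labels state a minimum depth of 100 reads, and the deposited tables also list sites below it.

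Samples were grouped by the genotype in the labels. The tests, the alternatives and the rule for named sites were fixed before the data were examined. Autosomal sites with at least 100 reads in all 12 adenomas were kept (8322), and 626 with reads of 1 state alone were left out. The 7696 sites left were tested with edgeR 4.0.16 in R 4.3.3: a quasi-likelihood test on methylated and unmethylated counts with 1 depth coefficient per adenoma, methylated-count coefficients per genotype, equal library sizes for both counts of an adenoma and dispersion without a trend (common dispersion 0.107). All 12 adenomas entered 1 fit with no covariate. Tests were two-sided with Benjamini-Hochberg adjustment over sites and a threshold of 0.05. Differences are in percentage points of the adjusted level, and values are mean ± SD over 3 adenomas. Single values per adenoma were compared with exact permutation tests, which cannot go below 0.10 for 3 against 3. Alternatives were depth minimums of 20, 50 and 300 reads, limma 3.58.1 on log2 ratios of counts with 2 reads added to each, limma on the logit of the adjusted percent level, a quasi-binomial model, fits of the compared adenomas alone, replicate number as a block, limits on level, X included, chromosome 10 left out, centred values, and leaving out each adenoma. Alternatives added after the data were seen were leaving out the shallow library, sex as a covariate and reads summed over runs of sites; classes of sites below 5% and of 5 to 20%, and by number of neighbouring sites, were also added then. The standards were taken as unmethylated or methylated by their own level, 0.12 to 1.66% for the first and 98.7 to 99.2% for the second. Figures were drawn with matplotlib 3.10.9.

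Named sites were, per comparison with control, up to 10 rises and 10 falls with the largest difference among changed sites whose mutant values all lay on one side of all control values. Where none passed, the 5 sites with the smallest p in each direction were taken. For other comparisons the 3 largest in each direction were taken. The part of the rule that allows 1 site per gene was not applied. The gene table at hand is of the GRCm38.p6 assembly, and coordinates were not converted, so sites are given by mm9 position and were not assigned to genes. Gene lists, cell type markers, sites in the targeted genes, CpG islands and windows around Tet1 and Tdg were therefore not analysed here. The absence of Tet1 was thus taken from the labels and not checked in these libraries.

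The tests were run on simulated counts for 7285 sites, with 100 sites changed at each of 2 sizes. For Tet1 null against control, edgeR recovered 5 of 100 sites with an odds fold of 2.72 and 86 of 100 with 7.39, and 6.19% of its calls were false. Limma recovered 2 and 69 of 100 and the quasi-binomial model 21 and 81 of 100. With unchanged groups (7318 sites) all 3 made 0 calls in the 7 comparisons, at an adjusted p under 0.05. Sites were simulated independently, with no shift shared over the sites of an adenoma. The changed sites were not drawn from the lowest or the high levels. The 0 calls hold for that setting only: a regrouping of the real double heterozygous and Tdg heterozygous adenomas across genotypes gave 14 sites (edgeR). Total reads were 2349576 to 18865833 per adenoma, and the median depth at tested sites 141 to 1233 reads. The labels name no molecular identifiers, so intervals cover counting error only. Replicates were compared first: methylation levels differed at 17.3 to 35.3% of tested sites between adenomas of a genotype (chi-square p under 0.05), so no pair looked like 1 library deposited more than once. Reads on the Y chromosome numbered 0 to 10 in 5 adenomas and 485 to 3281 in 7, and sex was taken from them. Control 1, Tet1 null 1 and 2, Tdg heterozygous 2 and all double heterozygous adenomas were male. X and Y sites were left out of the main tests.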

Results

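DNA methylation was measured in 12 colonic adenomas of C57BL/6J mice carrying the Min allele of Apc, the tumour suppressor whose loss starts intestinal adenomas. Tet1 is a dioxygenase that oxidises 5-methylcytosine, and Tdg is a DNA glycosylase that removes the oxidised bases. The adenomas came from 4 genotypes with 3 adenomas each: control (wild type for Tet1 and Tdg), Tet1 null, Tdg heterozygous for the N151A mutation (Tdg heterozygous below), and heterozygous for both Tet1 and Tdg N151A (double heterozygous below). Mice were 150 to 160 days old. Methylation levels at CCCGGG sites came from digital restriction enzyme analysis of methylation, which counts reads cut while unmethylated and reads cut while methylated. Total reads were 16551619, 16881059 and 12639191 in the control adenomas, 16812476, 18527831 and 8213211 in the Tet1 null and 18521326, 18865833 and 15404336 in the Tdg heterozygous adenomas. They were 17146721, 17729712 and 2349576 in the double heterozygous adenomas, the last of which had a median of 141 reads at the tested sites. Of 164896 autosomal sites, 8322 had at least 100 reads in every adenoma and 7696 of these were tested. The labels do not say whether the adenomas came from separate mice, so p-values measure the spread between these adenomas. By their Y chromosome reads, 3 of the genotypes held adenomas of both sexes, and all double heterozygous adenomas were male.

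The first comparison asked which sites differ in methylation when Tet1 is absent. Methylation rose at 201 sites in Tet1 null adenomas and fell at 2 sites, out of 7696 (edgeR, adjusted p under 0.05). The median rise was 12.4 percentage points (interquartile range 4.65 to 25.6), from a median level of 2.78% in control to 15.9% in Tet1 null adenomas. The rise was at least 10 points at 113 sites and at least 20 points at 68 sites. Of sites with a mean level below 20% over all 12 adenomas, 159 of 5677 rose (2.80%). So did 38 of 1363 sites at 20 to 80% (2.79%) and 4 of 656 sites above 80% (0.610%). The mean includes the Tet1 null adenomas, so a large rise can itself move a site up a class. These shares therefore do not compare sites by their level in control. Sites with 0 or 1 other CCCGGG site within 500 bp rose at 144 of 4605 (3.13%), those with 2 at 47 of 1788 (2.63%) and those with 3 or more at 10 of 1303 (0.767%). The 203 changed sites fell in 161 of 4066 runs of tested sites no more than 500 bp apart, and 40 of these runs held at least 2 of them. At 183 of the 201 sites, all 3 Tet1 null values lay above all 3 control values. Over all 7696 sites, 13.02% separated the groups in this way in either direction, 935 higher and 67 lower in Tet1 null adenomas. The 10% given by chance holds only without tied values, so it is not a firm reference here. Against control the share was 7.37% for Tdg heterozygous and 7.09% for double heterozygous adenomas, and it was 5.05% between these genotypes. At an unadjusted p under 0.05 there were 787 sites. Limma called 51 sites, all among the 203. The count was 6 of 125 sites at a depth minimum of 300 reads, 1 of them among the 203. It was 6 with limma on values centred on sites of 20 to 80%. Without 1 adenoma the edgeR count was 127 (control 1), 104 (control 2), 98 (control 3), 229 (Tet1 null 1), 111 (Tet1 null 2) or 100 (Tet1 null 3).

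**Figure D1:**
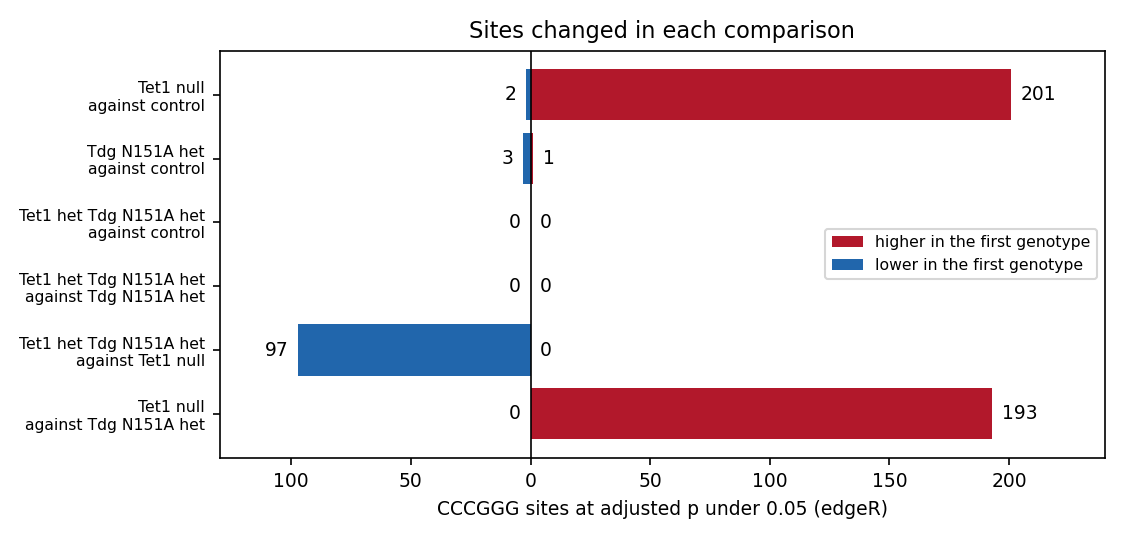
Bars give the number of CCCGGG sites that changed in each comparison of 2 genotypes (edgeR, adjusted p under 0.05, 7696 sites tested), with sites higher in the first genotype named on the vertical axis to the right of 0 and lower sites to the left. Comparisons with Tet1 null adenomas gave 203, 97 and 193 changed sites, and the remaining 3 comparisons gave 4, 0 and 0.

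The largest rises were at 2 neighbouring sites on chromosome 16 (mm9). At position 35660144 the level was 84.6% ± 10.9 (SD, n = 3) in Tet1 null adenomas and 11.2% ± 0.729 in control (edgeR adjusted p = 5.74e-16). At position 35660504 it was 73.3% ± 18.3 against 2.82% ± 1.38 (edgeR adjusted p = 9.68e-21). The level at position 35660144 was 10.3% ± 0.303 in Tdg heterozygous and 18.5% ± 1.13 in double heterozygous adenomas. The sites lie within 500 bp of each other and are not independent, and the values rested on 124 to 1452 reads per adenoma and site. On chromosome 3, position 118138315 rose from 14.3% ± 13.9 to 78.8% ± 20.01, and on chromosome 18, position 43741702 rose from 26.3% ± 10.6 to 87.8% ± 7.92. On chromosome 8, position 10154587 rose from 9.40% ± 5.86 to 64.3% ± 10.8. A run of 4 tested sites on chromosome 14 between positions 109311177 and 109312055 held 3 sites that rose, with a mean level of 4.81% in control and 35.9% in Tet1 null adenomas, and the site at position 109311177 rose from 2.71% to 50.1%. The remaining 4 of the 10 largest rises were at positions 75856108 on chromosome 14 (44.3 points), 144519106 on chromosome 5 (42.3 points), and 72636773 and 72612909 on chromosome 8 (41.0 and 40.1 points). The adjusted p of limma was 0.055 at positions 144519106 and 72612909 and 0.0697 at 72636773. On chromosome 12, position 112513755 fell by 5.90 points, from 6.13% ± 7.72 to 0.23% ± 0.204, and was not called by limma (adjusted p = 0.313). The second site that fell, at position 73605205 on chromosome 13, fell by 0.38 points and was singled out after its values were seen.

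**Figure D2:**
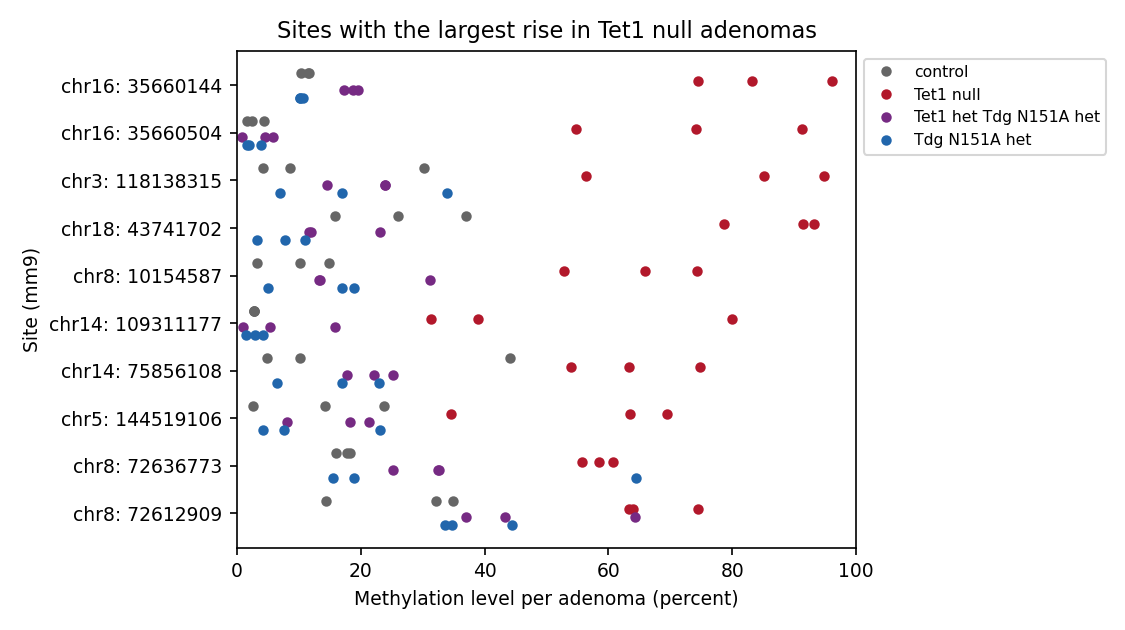
Each point is the adjusted methylation level in percent of 1 adenoma at 1 of the 10 sites with the largest rise in Tet1 null adenomas (mm9 positions on the vertical axis), coloured by genotype, 3 adenomas each. At the 2 chromosome 16 sites the Tet1 null adenomas lay between 54.7 and 96.2%, above the adenomas of the other genotypes.

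The next comparison asked what the Tdg N151A mutation on 1 allele changes. Methylation fell at 3 sites and rose at 1 site in Tdg heterozygous adenomas. The largest fall was at position 82565815 on chromosome 18, from 83.3% ± 8.63 to 48.1% ± 6.96 (n = 3 each, edgeR adjusted p = 0.0478), while Tet1 null adenomas were at 83.7% ± 9.87. On chromosome 4, the neighbouring positions 59048045 and 59048357 fell by 8.48 and 8.22 points, to 0.83% and 0.823%, with control SDs of 10.5 and 10.3 points (edgeR adjusted p = 0.0161 at each). The rise, singled out after its values were seen, was 5.49 points at position 74521190 on chromosome 2. There were 253 sites at an unadjusted p under 0.05, limma and the quasi-binomial model called 0 sites, and the count was 0 without Tdg heterozygous adenoma 1, 2 without adenoma 2, 1 without adenoma 3 and 1 without control 2. It was also 0 when the shallow double heterozygous adenoma 3 was left out of the fit.

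The double heterozygous adenomas carried 1 mutated allele of both genes. No site was called as changed against control by edgeR (0 of 7696, 281 at an unadjusted p under 0.05), by limma or by a quasi-binomial model. Recovery of simulated changes was measured for Tet1 null adenomas alone, so how many changes this comparison would miss is not known. The sites with the smallest p did not pass, with an edgeR adjusted p of 0.243 for the first of them. Among these, position 82262520 on chromosome 11 was at 87.6% ± 1.47 in double heterozygous and 53.2% ± 31.4 in control adenomas, and position 77864691 on chromosome 15 at 86.8% ± 2.47 and 57.0% ± 9.59. Position 37635258 on chromosome 5 was at 9.82% ± 5.34 and 1.87% ± 0.951. Among the sites that were lower, position 107348818 on chromosome 4 was at 27.6% ± 9.17 against 53.7% ± 12.6 (edgeR adjusted p = 0.881). The count was 3 without control 2, 2 without control 3, 1 without double heterozygous adenoma 1, and 4 with sex as a covariate. With 26 X chromosome sites included it was 23, with 3 autosomal sites higher and 20 X chromosome sites lower in these male adenomas.

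The mutant genotypes were also set against each other. Against Tet1 null adenomas, 97 sites fell and 0 rose in double heterozygous adenomas, by a median of 18.2 points from 22.9% to 3.47%. The largest falls were at position 43741702 on chromosome 18 (87.8% to 15.5%), and at positions 35660504 and 35660144 on chromosome 16. Between Tet1 null and Tdg heterozygous adenomas, 193 sites differed and all were higher in Tet1 null adenomas, by a median of 13.4 points. The same 3 positions led, and position 43741702 differed by 80.5 points (edgeR adjusted p = 3.0e-22). Of the 201 sites that rose against control, 138 were among these 193, where independent lists would share 5.04, and 78 were among the 97, where independent lists would share 2.53; the lists share the Tet1 null adenomas. Double heterozygous and Tdg heterozygous adenomas differed at 0 sites by edgeR, with 216 at an unadjusted p under 0.05, and at 0 by limma and the quasi-binomial model (1 by edgeR without Tdg heterozygous 3, 19 with X chromosome sites included, all on X and lower in double heterozygous adenomas). Limma called 20 sites in the comparison with 97 and 94 in that with 193. The 97 sites became 61 without Tet1 null 3, 48 without double heterozygous 2 and 59 without double heterozygous 3, and the 193 became 125 without Tet1 null 3 and 126 without Tdg heterozygous 1.

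Set together against control, the mean of the 3 mutant genotypes was higher at 9 sites and lower at 0 (edgeR). Among these 9, only position 76589461 on chromosome 2 had all 9 mutant values above the 3 control values, at 93.7% ± 3.02 in control and 98.7 to 99.2% in the mutant group means (edgeR adjusted p = 0.0104). The remaining 8 sites included positions 35660144, 35660504, 118138315, 10154587 and 109311177 named above for Tet1 null adenomas. There were 458 sites at an unadjusted p under 0.05, and limma and the quasi-binomial model called 0. The count was 2 without control 2, 3 without control 3, 14 without Tet1 null 1 and 5 without Tdg heterozygous 1. With X chromosome sites included, 10 sites were higher and 15 lower, and 14 of the lower sites were on X.

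Methylation was also compared as 1 value per adenoma. The mean level over all 7696 sites was 17.1% ± 0.28 in control, 19.1% ± 1.49 in Tet1 null, 17.7% ± 0.54 in Tdg heterozygous and 18.3% ± 1.14 in double heterozygous adenomas (SD, n = 3). In each mutant genotype all 3 values lay above the 3 control values, which gives the smallest p that 3 against 3 allows (two-sided exact permutation p = 0.10 for each, adjusted 0.138 for Tet1 null, 0.22 for Tdg heterozygous and 0.157 for double heterozygous over 11 measures). All 9 mutant adenomas against 3 controls gave an exact permutation p of 0.0818 (adjusted 0.143). Sites at 20 to 80% were at 47.4% ± 1.21 in control, 54.3% ± 5.98 in Tet1 null, 49.9% ± 1.99 in Tdg heterozygous and 52.4% ± 3.92 in double heterozygous adenomas. Sites above 80% lay between 88.5% and 89.9% in the group means. Sites below 5% were at 0.368% ± 0.014 in control and 0.623% ± 0.11 in Tet1 null adenomas, and at 0.394% and 0.425% in Tdg and double heterozygous adenomas. Gains were counted as sites below 5% in a pair of controls and at 15% or more in the adenoma. They made up 0.603% ± 0.12 of sites in Tet1 null adenomas, 0.10% ± 0.069 in control, 0.0827% ± 0.074 in Tdg heterozygous and 0.0737% ± 0.070 in double heterozygous adenomas (exact permutation p = 0.10 for Tet1 null, n = 3). The 3 Tet1 null adenomas gained at 0.469% (95% Clopper-Pearson interval 0.293 to 0.693), 0.710% (0.491 to 0.977) and 0.630% (0.424 to 0.884), intervals that cover counting error only. Losses, from above 80% in the controls to 60% or less, were at 1.03% ± 0.82 of sites in control and at 0.659% ± 1.04, 1.18% ± 1.06 and 0.348% ± 0.46 in Tet1 null, Tdg heterozygous and double heterozygous adenomas (exact permutation p = 0.50, 0.90 and 0.30, n = 3 each). Single adenomas ranged from 0.394 to 1.96% in control and from 0 to 2.23% in the mutant genotypes.

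**Figure D3:**
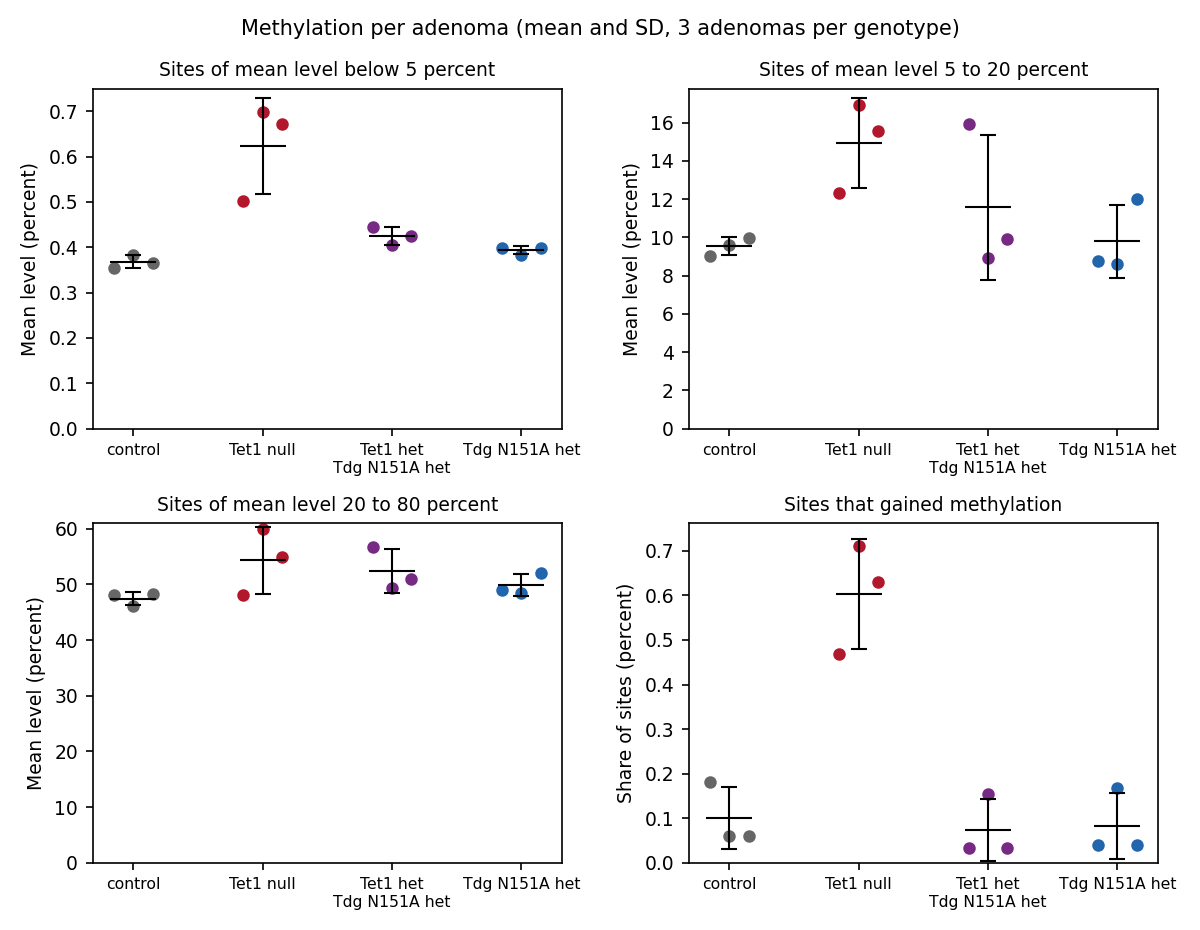
Points are single adenomas of each genotype on the horizontal axis, with mean and SD of 3 adenomas as lines. Vertical axes give the mean methylation level in percent for sites below 5%, at 5 to 20% and at 20 to 80% (mean over all 12 adenomas), and the share of sites in percent that gained methylation, where Tet1 null adenomas lay between 0.469 and 0.710% and the others between 0.034 and 0.180%.

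Tet1 and Tdg both lie on chromosome 10, where 10 of 422 tested sites changed in Tet1 null adenomas (2.37%, against 2.65% elsewhere, Fisher's exact p = 0.876). The largest shares were on chromosome 6 (18 of 334, 5.39%) and chromosome 14 (15 of 274, 5.47%), neither past the threshold over 19 chromosomes (Fisher's exact test, adjusted p = 0.0605 for both). Chromosome 14 held 10 of the 97 sites lower in double heterozygous than Tet1 null adenomas (odds ratio 3.19, Fisher's exact test, adjusted p = 0.0432), and neighbouring sites are not independent in these tests. None of the sites changed in Tdg heterozygous adenomas was among the 203 of Tet1 null adenomas. Differences from the shared controls correlated across sites, which are not independent replicates, with r = 0.336 for Tet1 null and Tdg heterozygous, 0.304 for Tet1 null and double heterozygous and 0.306 for both heterozygous genotypes. Simulated unchanged groups that shared simulated controls gave 0.470, 0.477 and 0.314, and the observed covariances of 0.0965, 0.0942 and 0.0723 lay below the simulated 0.118, 0.142 and 0.0960. The simulated controls took a spread per site pooled over all genotypes. If the real controls vary less than that, lower covariances follow from the setting, so no conclusion was drawn from them.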

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

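Tests of the standards, sex, labels and splits were chosen or written down after the result was seen; thinning of reads and the covariate were written down before, except the bound for sites still called after thinning. 2 contrasts with Tet1 null adenomas differed by a test of the difference itself: 193 sites against Tdg heterozygous adenomas and 97 sites against double heterozygous adenomas (edgeR, adjusted p under 0.05).

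For the rise at 201 sites in Tet1 null adenomas, incomplete cutting by SmaI would raise unmethylated sites, but the unmethylated standard read at most 1.29% in a Tet1 null library, against a median rise of 12.4 points. Sex does not account for the larger share of gaining sites, which was at most 0.180% in a male adenoma of the other genotypes. It was 0.630% in the female Tet1 null adenoma and 0.469 and 0.710% in the male ones. This rests on 1 female Tet1 null adenoma and does not cover each of the 201 sites. With sex as a covariate, fewer sites than 203 were called (count given below), so a part of sex at single sites stays open. With every library thinned to the same depth at each site, 85 of the 203 sites were still called, which unequal depth cannot give; this is 41.9%, and the loss of the other 118 cannot be told apart from the loss of reads. A biological effect of Tet1 loss, which the design names, stays a hypothesis, and a different share of adenoma cells stays open, since 31.0% of the sites (63 of 203) were still called with the level of sites at 20 to 80% as a covariate, between the bounds set for the test. With this covariate, 123 of 193 sites (Tet1 null against Tdg heterozygous) and 89 of 97 sites (double heterozygous against Tet1 null) were still called. These counts cannot decide, since the covariate was not shown to follow the share of adenoma cells. It also differed little between double heterozygous and Tet1 null adenomas (52.4% ± 3.92 and 54.3% ± 5.98). Tet1 null 1 was at 48.0% in the covariate (control 46.1 to 48.2%). At sites higher in Tet1 null than Tdg heterozygous adenomas, chosen without it, it was at 24.0 to 26.3% (control means 10.4 to 13.8%). If the covariate follows the share of adenoma cells, this goes against that explanation for this 1 adenoma.

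The second pattern was that double heterozygous adenoma 1 stood apart at sites of 5 to 20%, at 15.9% where the other 2 double heterozygous adenomas were at 8.91% and 9.89%, and the Tet1 null adenomas at 12.3 to 16.9%. A Tet1 null library under a wrong label is argued against by the 193 sites higher in Tet1 null than Tdg heterozygous adenomas, where double heterozygous adenoma 1 was at 11.5%, against 22.9 to 25.98% in Tet1 null and 8.51 to 11.9% in control adenomas. Choosing these sites raised the Tet1 null range. At sites chosen without it, a Tet1 null adenoma was at 23.3 to 32.9%, and the double heterozygous mean was 9.13 to 16.1%. The level of double heterozygous adenoma 1 alone was not taken at those sites. Incomplete cutting is argued against by an excess over control of 6.38 points, with the unmethylated standard at 1.66% in this library. No biological explanation was tested.

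Other splits of the same 6 adenomas number 10 with the real one, too few for a share under 0.05. Tet1 null against control gave 203 sites and the highest other split 9 (1 of 10 as large). Tet1 null against Tdg heterozygous gave 193 and 13 (1 of 10), and double heterozygous against Tet1 null 97 and 24 (1 of 10). Tdg heterozygous against control gave 4 and 6 (2 of 10), double heterozygous against control 0 and 3 (10 of 10), and double against Tdg heterozygous 0 and 14 (10 of 10). For the mean of the 3 mutant genotypes, 33 of 100 splits gave at least the 9 sites seen, so chance cannot be excluded. The highest other split gave 288 sites and set the 3 Tet1 null adenomas apart from the other 9, a structure of the samples.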

How the results depend on the processing

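Leaving out the shallow library, sex as a covariate and sums over runs of sites were chosen after seeing the data; the other alternatives were set before. Counts of changed sites are given for Tet1 null, Tdg heterozygous and double heterozygous against control, double heterozygous against Tdg heterozygous and against Tet1 null, Tet1 null against Tdg heterozygous, and the mean of the mutant genotypes against control, which were 203, 4, 0, 0, 97, 193 and 9. Of 166 alternative counts, 85 stayed within 1.5 times and 81 did not. Except where fewer sites or adenomas entered by construction, the cause was not tested.

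With a difference of at least 10 points, 113, 1 and 112 sites were left for Tet1 null and Tdg heterozygous against control and Tet1 null against Tdg heterozygous. With at least 20 points, 68, 1, 46, 70 and 5 were left, in the order above without the comparisons at 0. A depth minimum of 20 reads gave 311 for Tet1 null against control, 1 for double heterozygous against control, 314 for Tet1 null against Tdg heterozygous and 17 for the mean. A minimum of 50 gave 1 for double heterozygous against control and 291 for Tet1 null against Tdg heterozygous. A minimum of 300, with 125 sites tested, gave 6, 0, 1, 5 and 0. In the same order, limma gave 51, 0, 20, 94 and 0, limma on the adjusted level 89, 0, 44, 99 and 0, and sites of 5 to 95% alone 58, 0, 16, 87 and 0. Centred limma values gave 6, 0, 5, 18 and 0, and sums over runs of sites 114, 0, 52, 124 and 1. The quasi-binomial model gave 101, 0, 28 and 0, and 139 for Tet1 null against Tdg heterozygous. With X included, Tdg heterozygous against control gave 2, double heterozygous against control 23 and against Tdg heterozygous 19, and the mean 25. Tet1 null against control then gave 192 sites higher and 16 lower, double heterozygous against control 3 and 20, and the mean 10 and 15, and 14, 20 and 14 of the lower sites were on X. Tet1 null against Tdg heterozygous gave 186 higher and 12 lower, and all 12 lower sites were on X. The genotypes differed in sex, and X chromosome sites were lower in male adenomas. With sex as a covariate, Tdg heterozygous against control gave 2 and double heterozygous against control 4, and Tet1 null against control 166. Without the shallow library Tdg heterozygous against control gave 0. Leaving out 1 adenoma gave 98 to 229, 0 to 5, 0 to 3, 0 to 1, 48 to 123, 125 to 203 and 2 to 14 for the 7 comparisons.

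With replicate number as a block, Tet1 null against control gave 111, Tdg heterozygous against control 2, double heterozygous against Tet1 null 60, Tet1 null against Tdg heterozygous 137 and the mean 0. The numbers were not taken to pair the adenomas: only 6 of 18 pairs with the same number had correlated deviations above 0.1 (r from -0.157 to 0.420), and 5 of 12 adenomas correlated best with one of their own number.

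Of 316 alternative levels and shares per adenoma, 299 kept their side of the threshold without a reversed direction, 15 changed direction and 2 came to pass. Tests of 3 against 3 adenomas or fewer cannot reach 0.05, so for these only the direction was free to change. The share of gaining sites in Tdg heterozygous minus control was 7.71e-05 points at 50 reads and 7.15e-05 without the shallow library, and -0.159 to 0.00346 when 1 adenoma was left out. That of double heterozygous minus control was 0.132 with gains counted from 10% and 0.0179 without the shallow library. The share of losing sites in Tdg heterozygous minus control was -0.349 with losses from above 90 to at most 70%, and -1.32 to 0.669 when 1 adenoma was left out. At 300 reads, the level of sites below 20% was -0.0925 for Tdg heterozygous minus control, and that of sites above 80% was -1.11 for Tet1 null and -0.0133 for the mean. Leaving out 1 adenoma gave, for Tet1 null, Tdg heterozygous and double heterozygous minus control, 1.31 to 2.79, 0.259 to 0.735 and 0.579 to 1.65 over all sites. It gave 4.0 to 9.99, 1.30 to 3.15 and 2.80 to 6.51 at 20 to 80%, and 0.388 to 2.14, 0.769 to 1.55 and 0.901 to 1.73 above 80%. Below 20% it gave 0.784 to 1.14, -0.0960 to 0.132 and 0.0157 to 0.475, and for the mean 3.77 to 5.25 at 20 to 80% and 0.804 to 1.58 above 80%. The last 2 passed without Tet1 null 1 (exact permutation p = 0.0485 and 0.0182, n = 8 and 3). Differences in gaining and losing sites were 0 at 300 reads, where 125 sites were tested. These have no direction and are counted among the 299.

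For 41 named pairs of a site and a comparison, some at the same site, 770 alternative values were taken. Of these, 693 kept their side of the threshold. The count that changed direction was 0, but this was fixed in advance. Direction came from the difference in mean level, which the choice of test does not alter. Pairs that passed had been chosen with all values of their groups apart, so leaving out an adenoma could not alter it either. Another 8 came to pass, and 69 values of 12 pairs no longer passed. The 41 pairs include those of double heterozygous adenomas against control and against Tdg heterozygous adenomas, where 0 sites changed (smallest edgeR adjusted p 0.243 and 0.850). None of these had passed in the main tests, so none could stop passing or be counted as changed in direction. The 12 pairs therefore come from the other comparisons alone, and the 693 values overstate how stable the sites that passed were. Not run were gene lists, promoter sites and windows of chromosome 10 around the targeted genes, since sites were not assigned to genes. Depth limits double heterozygous adenoma 3, and with it which sites could be tested in all adenomas.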

Other observations

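All tests here were chosen after the data were seen. Tet1 null adenomas were set against the other 9 adenomas together. The share of sites that gained methylation was 0.603% ± 0.12 (n = 3) against 0.0856% ± 0.062 (n = 9), with every Tet1 null adenoma above all others. This grouping was made after the values were seen to lie apart, so no p is given. The mean level of sites below 5% was 0.623% ± 0.11 against 0.395% ± 0.028 (n = 3 and 9). Values of Tet1 null and the other adenomas overlapped for sites at 20 to 80% (48.0 to 59.9% and 46.1 to 56.8%) and above 80% (87.9 to 91.1% and 87.5 to 90.97%).

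A hypothesis was that 1 mutated Tet1 allele gives an intermediate rise at the same sites. Double heterozygous adenomas carry it with the Tdg mutation, so against control its effect was not isolated. Against Tdg heterozygous adenomas the genotypes differ in this allele alone, although the sex of the adenomas also differs. At the 193 sites that were higher in Tet1 null than Tdg heterozygous adenomas, double heterozygous adenomas were 0.976 points above control (10.7% ± 0.74 and 9.77% ± 1.86, SD, exact permutation p = 0.50, n = 3), with 131 sites higher and 58 lower. Choosing the sites raises the Tet1 null mean (24.4% ± 1.55). They were therefore chosen again without 1 Tet1 null and 1 Tdg heterozygous adenoma, in 9 ways that share adenomas. Midway from control to the Tet1 null adenoma left out was 5.08 to 9.24 points. Double heterozygous minus control plus 2 standard errors was 3.31 to 4.59 points, lower in each, with the closest at 4.59 against 5.08. Above the Tdg heterozygous adenoma left out, midway was 4.68 to 9.74 points and double heterozygous adenomas were at 0.653 to 2.33. Each midway value rests on single adenomas, and 2 standard errors are a narrow bound for 3 against 3. The values lie below a rise of midway size in double heterozygous adenomas at these sites without excluding it, and a smaller one stays open. Toward a smaller one go 3.29 points above Tdg heterozygous adenomas at the 193 sites (163 higher and 27 lower) and 2.88 points above control at the 201 sites that rose in Tet1 null adenomas (159 higher and 38 lower, exact permutation p = 0.10 for both, n = 3). These lists were chosen with the lower group in their contrast, which lowers its mean. At the 201 sites, where neither group was in the contrast, double heterozygous were 1.67 points above Tdg heterozygous adenomas (141 higher and 59 lower, exact permutation p = 0.10, n = 3). Over all 731 sites of 5 to 20% they were 1.78 points above Tdg heterozygous adenomas (11.6% ± 3.78 and 9.79% ± 1.91, exact permutation p = 0.50, n = 3). There they were 2.04 points above control (exact permutation p = 0.70, n = 3). The gaps are thus not shown to be particular to the sites that rose in Tet1 null adenomas.

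X chromosome sites with at least 20 reads in all adenomas (327 sites) had a mean level of 40.6% ± 1.23 in the 5 female and 22.6% ± 0.78 in the 7 male adenomas (two-sided exact permutation p = 0.00126, the smallest that 792 splits can give).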
